A study of Homo sapiens with 6 samples.

How the data were processed

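RNA from A375 and Colo800, both human melanoma cell lines, was profiled by RNA sequencing after infection with viruses carrying 1 of 3 short hairpin RNAs: a scrambled hairpin and 2 hairpins against the ETS-family transcription factor ETV1, named ETV1-sh1 and ETV1-sh2 in the labels. Per the series' design text, infections were made in duplicate and RNA was taken 4 days after infection. The table analysed holds 1 column per line and hairpin, and whether that column pools the duplicates is not given in the sources used here. The labels conflict on one point. Their treatment field gives the ETV1-sh1 samples as DMSO, the ETV1-sh2 samples as 5 nM trametinib (a MEK inhibitor) and the scrambled samples as 1 uM vemurafenib (a BRAF inhibitor), and their protocol describes siRNA for 48 hours and drug for 8 hours. The design text names no drug. In these labels each drug goes with 1 hairpin, so a drug effect and a hairpin effect could not be separated by any model.

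The values are FPKM (fragments per kilobase of transcript, scaled to the size of the library) made by the authors with STAR 2.4, Cufflinks 2.2.1 and Cuffnorm on the hg19 build, per the submitters' processing notes. The gene annotation, any filter, the Cuffnorm scaling method and the strandedness are not given in the sources used here, so overlapping and antisense genes, and near-identical gene copies, cannot be told apart with certainty. The deposited FPKM table has 17468 genes, each with an Ensembl identifier and a symbol, and the symbols were used as given. The reference gene names held 17037 of these identifiers, 16157 of them with the same symbol. The reference genome used here is GRCh38, not the build of the files, so no coordinates are given. It served only for 3′ UTR sequences, from GENCODE release 29, matched by Ensembl identifier.

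FPKM values carry no absolute depth. Among low genes the values of 2 libraries stand in a commonest ratio, the ratio of what 1 fragment is worth in each. Between 1272 and 1882 genes with values from 0.0001 to 0.3 in both libraries were compared with the A375 scrambled library for this. The commonest ratio held for 7.13% to 9.88% of them. Of the values, 26 lay above 0 and below 1e-200, as likelihood estimates can, so an exact 0 is described only as listed at 0.

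Tests used limma 3.58.1 in R 4.3.3, with moderated statistics (lmFit, then eBayes with a variance trend) on log2(FPKM + 1), in the 11129 genes with a mean FPKM of at least 1 over the 6 libraries. A fold change on this scale understates the change of low genes. P-values were adjusted by the Benjamini-Hochberg method and 0.05 was the threshold. ETV1 hairpins against scrambled was fitted with the cell line as a block (4 libraries against 2, 3 residual degrees of freedom). In that fit the lines and the hairpins are the replication, and any effect of 1 hairpin alone or 1 line alone counts as residual spread. The difference of this effect between lines came from a fit with a mean per line and knockdown state (2 residual degrees of freedom). ETV1-sh2 against ETV1-sh1 and Colo800 against A375 came from a fit with the cell line and 3 hairpin levels (2 residual degrees of freedom). These designs were fixed before the data were examined. Each ETV1 hairpin against scrambled in the 3-level fit was added after the data were seen. Nothing in the labels says how far the libraries of a line are separate cultures, so p-values measure the spread between these 6 libraries. Within a line no test was made: a gene was counted when both ETV1 hairpins changed it at least 2-fold in the same direction against the scrambled library.

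The 33 gene lists were written before the data were examined, and 773 of their 793 entries were found in the table. A total of 32 lists with at least 3 expressed members were tested with camera (preset inter-gene correlation of 0.01, then estimated) and with fry, in its directional test unless the mixed one is named. For each library a list's median was also placed among 10000 random lists matched on mean expression. The genes named were chosen by rules fixed before the data were examined. They were ETV1; for ETV1 hairpins against scrambled, 12 genes per direction past the threshold, filled up, where fewer passed, by the smallest p among genes with all 4 hairpin differences in that direction and a fitted log2 change of at least 0.58; 2 to 4 members per list with the largest moderated statistic in that fit; 5 genes per direction, or 3 where none passed, for the other fits; and 6 per direction within a line. Genes named LOC or LINC and small RNAs were passed over. For each hairpin against scrambled the 10 genes per direction with the largest change past the threshold were taken, a rule set after the data were seen.

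Shared scrambled libraries were handled by simulation: 20 simulated data sets with no hairpin effect and the fitted spread were run through the same steps. On simulated data with 200 changed genes among 11129, the fit of ETV1 hairpins against scrambled recovered 23% of 2-fold and 98% of 4-fold changes with 8 false calls. The corresponding recoveries were 81% and 100% for ETV1-sh2 against ETV1-sh1, and 92% and 100% for Colo800 against A375. They were 71% and 100% for ETV1-sh1 against scrambled, and 78% and 100% for ETV1-sh2 against scrambled. The fit of the difference between lines recovered 0% at both sizes.

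A scan of 7-base words asked whether genes that carry a word in the 3′ UTR changed more with a hairpin than genes that do not. The longest annotated 3′ UTR was taken for each gene, which 98.2% of the tested genes had. Each hairpin's library was compared with the mean of the other libraries of its line, after a linear correction for 3′ UTR length and GC content. The 16184 words found in at least 50 genes were tested. In simulated data each of 10 planted words ranked first, and the lowest statistic in 20 scans without an effect was -4.80. The alternatives tried were a pseudocount of 0.1, no filter on low values, a mean FPKM of at least 5, quantile normalization, equal medians, no variance trend, no cell line term, each hairpin alone, each library left out, 1.5-fold and 3-fold limits, and genes without a 3′ UTR match, the last of which was added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 prepared the values, and matplotlib 3.10.9 drew the figures. Genes used to tell sex were kept out of all named genes, and 1 gene that the rules named is not reported here.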

Results

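Gene expression was measured by RNA sequencing in 6 libraries, 1 for each combination of 2 melanoma cell lines (A375 and Colo800) and 3 hairpins (scrambled, ETV1-sh1 and ETV1-sh2). There were therefore 4 libraries with an ETV1 hairpin and 2 scrambled libraries, and no replicate within a line and hairpin. Between 10418 and 11013 genes per library had an FPKM of at least 1, and the FPKM values summed to between 589256 and 710498. Absolute depth is unknown. From the steps between low values, the depth relative to the A375 scrambled library was 1.43 for A375 ETV1-sh1, 2.10 for A375 ETV1-sh2, 0.803 for Colo800 scrambled, 0.861 for Colo800 ETV1-sh1 and 0.771 for Colo800 ETV1-sh2. Cytosolic ribosomal protein genes took 15.1% to 18.0% of the FPKM sum in A375 and 5.97% to 8.34% in Colo800, and mitochondrially encoded genes 3.83% to 5.03% and 6.15% to 9.21%. Across genes, the log2 values of libraries of one line correlated at 0.923 to 0.969.

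ETV1 (ENSG00000006468) encodes the ETS-family transcription factor that the hairpins target, and its level checks the labels. ETV1 was at 82.8 FPKM in the A375 scrambled library, 34.6 with ETV1-sh1 and 3.46 with ETV1-sh2, so that 41.8% and 4.18% of the scrambled level were left. In Colo800 it was at 180.3 FPKM with the scrambled hairpin, 54.6 with ETV1-sh1 (30.3% left) and 9.80 with ETV1-sh2 (5.43% left). Over both hairpins the fitted log2 change was -2.81 (SE 0.938), with an adjusted p of 0.414 in the limma fit, whose spread includes the gap between the hairpins. With each hairpin set alone against scrambled, ETV1 fell by 1.47 on the log2 scale with ETV1-sh1 (adjusted p = 0.00236) and by 4.15 with ETV1-sh2 (adjusted p = 0.0393). Each of those limma fits has 1 residual degree of freedom. In the limma fit with 3 hairpin levels the adjusted p of ETV1 was 0.0331 with ETV1-sh1 and 0.00299 with ETV1-sh2. ETV1 was lower in 4 of 4 hairpin libraries.

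**Figure D1:**
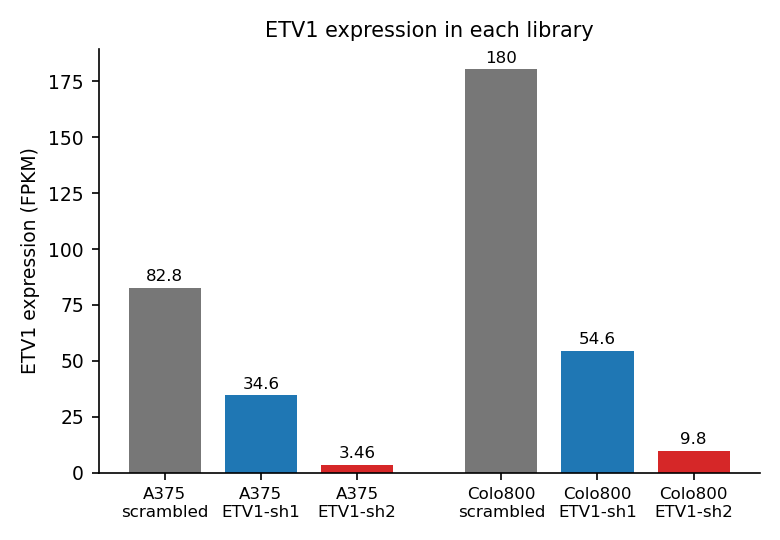
ETV1 expression (FPKM, y axis) in each of the 6 libraries (x axis; grey scrambled, blue ETV1-sh1, red ETV1-sh2; 1 library per bar, no error bars). In both lines the ETV1-sh2 library is lowest, at 3.46 and 9.80 FPKM.

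The comparison of ETV1 hairpins with scrambled asks which genes change when ETV1 is knocked down, whichever hairpin or line is used. No gene passed an adjusted p of 0.05 in limma. The smallest adjusted p was 0.135, and 567 genes lower and 637 higher had an unadjusted p under 0.05, against 556 in total that chance gives. That excess is not particular to the scrambled libraries. With the ETV1-sh1 libraries set apart in their place the fit gave 1033 such genes (2 past the adjusted threshold), and with ETV1-sh2 set apart 3226 (814). The genes named next were chosen among those that moved alike in all 4 hairpin libraries, so that agreement was fixed by the rule. TIMP3, an inhibitor of matrix metalloproteinases, stood at 424 FPKM in A375 scrambled against 23.8 and 21.3 with the hairpins, and at 844 in Colo800 scrambled against 183 and 219 (log2 change -3.12, SE 0.453, adjusted p = 0.263). PSAT1, an enzyme of serine synthesis, was at 30.1 FPKM against 6.36 and 5.80 in A375 and at 43.4 against 12.01 and 8.04 in Colo800 (log2 change -2.08, SE 0.237). HMGA2, a chromatin architectural protein, was at 779 against 318 and 284 in A375 and at 365 against 159 and 124 in Colo800. PABPC1, the cytoplasmic poly(A)-binding protein, was at 4028 FPKM against 1354 and 1796 in A375 and at 2251 against 828 and 906 in Colo800. The fitted log2 changes of the other named lower genes were -1.57 for the membrane-type metalloproteinase MMP16, -1.67 for PKNOX2, -1.48 for ARFIP1, -1.59 for CCDC59, -1.49 for PTMA, -1.52 for the TGF-beta pseudoreceptor BAMBI, -1.64 for MTX3 and -1.66 for FAM111B.

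On the higher side, DYNLRB1, a dynein light chain, was at 89.5 FPKM in A375 scrambled against 422 and 549 with the hairpins, and at 121 in Colo800 scrambled against 504 and 627 (log2 change 2.31, SE 0.209, adjusted p = 0.135). MED19, a Mediator subunit, was at 8.83 against 40.5 and 46.7 in A375 and at 6.34 against 27.4 and 30.97 in Colo800 (log2 change 2.11, SE 0.199). FURIN, a proprotein convertase, was at 30.4 against 97.4 and 106 in A375 and at 37.6 against 177 and 173 in Colo800 (log2 change 1.95, SE 0.195). The log2 changes of the other named higher genes were 1.66 for the homeobox gene HOXC6, 1.34 for HSD17B10, 1.36 for GPR157, 1.48 for HIP1R, 2.03 for the sorting nexin SNX15, 1.52 for the heme synthesis enzyme CPOX, 1.21 for GNG11, 1.48 for clusterin (CLU) and 1.31 for NKIRAS2. None of these 24 genes passed over all genes tested. With the ETV1-sh1 and scrambled libraries alone 489 genes fell and 316 rose, and with the ETV1-sh2 and scrambled libraries alone 527 fell and 363 rose. Each of those fits has 1 residual degree of freedom.

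**Figure D2:**
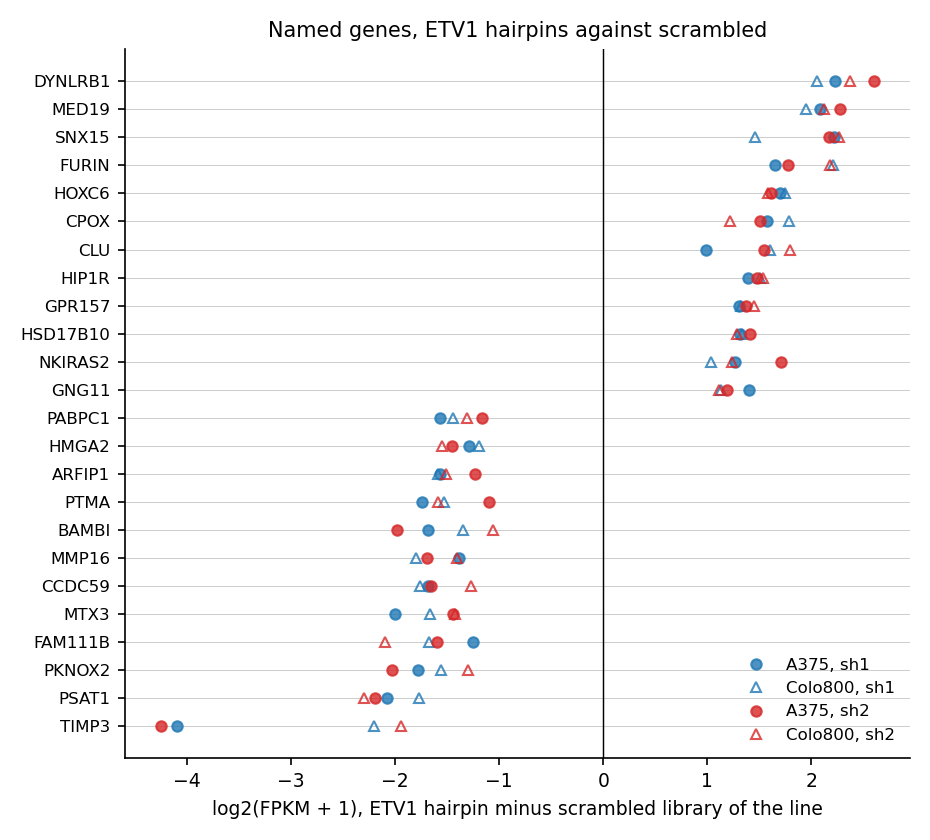
Change of the 24 named genes (y axis) in log2(FPKM + 1), each ETV1 hairpin library minus the scrambled library of its line (x axis). Blue marks are ETV1-sh1, red ETV1-sh2, filled circles A375 and open triangles Colo800. By the rule that chose the genes, all 4 marks of each lie on the same side of 0. SNX15 in Colo800 with ETV1-sh1 lies apart from its other 3 marks.

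The fixed gene lists were tested in the same comparison. With camera at its preset correlation 9 lists were lower and 1 was higher than other genes. With an estimated correlation none passed (smallest adjusted p = 0.694), nor with fry's directional test (smallest adjusted p = 0.585). Camera with an estimated correlation, here and in the fits below, rests on 2 or 3 residual degrees of freedom, so a miss there decides little. After ETV1-sh2 the DNA replication list went from a camera adjusted p of 1.37e-13 to 0.75 at an estimated correlation of only 0.038. For ETV1 hairpins against scrambled the estimates were 0.812 for proliferation, 0.65 for DNA replication, 0.656 for ribosome biogenesis and MYC and 0.636 for interferon response. The other lists that passed had estimates from 0.045 to 0.232. All lie above the preset 0.01, so p-values at the preset correlation are too small where such correlation holds. Fry's mixed test, for changes in either direction, passed for glycolysis and hypoxia (adjusted p = 0.000435) and integrated stress response (adjusted p = 0.0249). The proliferation list was lower in 28 of 28 members (median log2 change -1.17, camera adjusted p = 5.76e-13, adjusted p = 0.694 with an estimated correlation). No member passed over all genes and 5 passed when adjusted over the list alone: the spindle checkpoint gene MAD2L1 (-1.17), NUSAP1 (-1.18), HMMR (-2.04), BUB1B (-1.49) and topoisomerase TOP2A (-1.97). Of the DNA replication list 27 of 29 members were negative (median -0.77, camera adjusted p = 5.62e-08, 0.694 with an estimated correlation), with -1.85 for UHRF1, -0.86 for PCNA, -2.35 for RRM2 and -1.87 for MCM10. Of the ribosome biogenesis and MYC list 26 of 27 were negative (median -0.49, camera adjusted p = 5.62e-08, 0.694 with an estimated correlation), with -1.52 for MYC and -0.93 for the nucleolar protein NOP56.

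The interferon response list was the 1 higher list. Of its 30 members 28 were positive (median 0.80, camera adjusted p = 1.27e-06, adjusted p = 0.694 with an estimated correlation), with 1.58 for IFI44, 1.14 for the transcription factor IRF9, 0.94 for HERC6 and 1.08 for BST2. Of these IFI44 passed when adjusted over the list alone. The ERK output list, genes that follow MAP kinase signalling, was negative in 21 of 27 members (median -0.47, camera adjusted p = 1.72e-05, 0.694 with an estimated correlation). HMGA2 was at -1.37 in it, TFAP4 at -1.23, cyclin D1 (CCND1) at -1.44 and PHLDA1 at -0.54, and HMGA2 and TFAP4 passed when adjusted over the list alone. Glycolysis and hypoxia genes were negative in 23 of 27 (median -0.41, camera adjusted p = 3.25e-05, 0.694 with an estimated correlation), with -1.27 for PFKFB3, -1.38 for hexokinase HK2 and -0.85 for VEGFA, of which PFKFB3 and HK2 passed when adjusted over the list alone. Melanocyte lineage genes were negative in 19 of 24 (median -0.46, camera adjusted p = 0.000102, 0.694 with an estimated correlation), with -1.44 for MYO5A, -1.38 for S100B and -1.41 for ERBB3, which passed when adjusted over the list alone.

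Extracellular matrix and adhesion genes were negative in 28 of 37 (median -0.30, camera adjusted p = 0.00754, 0.694 with an estimated correlation), with -0.96 for LAMA4, -1.34 for ITGB3 and -1.16 for LAMC1 beside TIMP3, the member that passed when adjusted over the list alone. Integrated stress response genes were negative in 20 of 32 (median -0.19, camera adjusted p = 0.0185, 0.694 with an estimated correlation), with PSAT1, which passed when adjusted over the list alone, at -2.08 and the amino acid transporter SLC7A1 at 0.90. Unfolded protein response genes were negative in 15 of 22 (median -0.36, camera adjusted p = 0.0467, 0.718 with an estimated correlation), with -0.76 for HSP90B1 and -0.58 for HSPA5.

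The other lists did not pass with camera. Their median log2 changes were -0.28 for the ETS factors, which hold ETV1 itself, -0.36 for NF-kB and cytokines, -0.16 for p53 targets, -0.24 for housekeeping genes, -0.30 for TGF-beta and YAP targets, -0.25 for dedifferentiated melanoma genes and -0.32 for receptor tyrosine kinases. They were -0.09 for the cytosolic ribosome, -0.17 for heat shock, -0.11 for apoptosis regulators, -0.02 for the small RNA silencing machinery and 0.11 for lysosome and autophagy. They were 0.13 for replication-dependent histones, 0.07 for MAPK pathway components, 0.07 for cholesterol synthesis, 0.15 for immediate early genes, 0.13 for mitochondrially encoded genes and 0.06 for oxidative phosphorylation, whose mean was -0.04. Markers of other cell types had medians of 0.48 (fibroblast, 5 of 6 positive), 0.12 (keratinocyte), 0.12 (leukocyte) and -0.08 (epithelial, mean 0.23). The endothelial list had 2 expressed members and no list test, with KDR at 0.25 and TIE1 at 0.21. Adjusted over the list alone, ICAM1 (-1.19) passed in the NF-kB list, BAMBI (-1.52) and LATS2 (0.94) among TGF-beta and YAP targets, and ERBB3 (-1.41), EGFR (1.02) and DDR1 (1.39) among receptor tyrosine kinases; ICAM1, LATS2, EGFR, DDR1 and TOP2A were chosen after their values were seen.

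**Figure D3:**
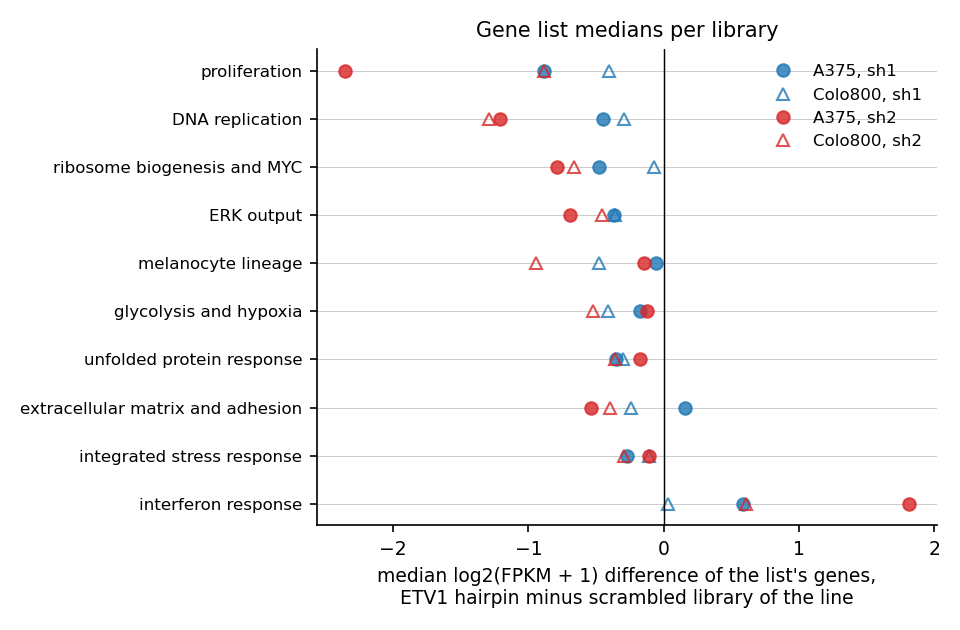
Median difference in log2(FPKM + 1) of each list's genes (x axis), ETV1 hairpin library minus scrambled library of the line, for the 10 lists that passed with camera at its preset correlation (y axis). Blue marks are ETV1-sh1, red ETV1-sh2, filled circles A375 and open triangles Colo800; the proliferation median runs from -2.36 (A375, ETV1-sh2) to -0.40 (Colo800, ETV1-sh1).

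The lists differed in size of change between libraries, each being a description of 1 library against 1. The proliferation median was -0.88 with ETV1-sh1 and -2.36 with ETV1-sh2 in A375, and -0.40 and -0.88 in Colo800, at or below percentile 0.01 of random lists each time. The interferon response median was 0.59 and 1.81 in A375, and 0.04 (percentile 58.6) and 0.61 in Colo800. The melanocyte lineage median was -0.06 (percentile 36.2) and -0.15 (percentile 13.6) in A375, and -0.48 and -0.95 in Colo800, below every random list. The cytosolic ribosome median was 0.11 and 0.33 with ETV1-sh1 in A375 and Colo800, and -0.28 and -0.43 with ETV1-sh2.

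Each hairpin was then set against scrambled in the fit with 3 hairpin levels, a comparison chosen after the data were seen. With ETV1-sh1 168 genes fell and 86 rose, and with ETV1-sh2 1002 fell and 860 rose. After ETV1-sh1 the lower genes with the largest changes were TIMP3 (log2 change -3.15), TMEM50A (-3.004), the lysyl oxidase-like enzyme LOXL4 (-2.78), the myelin protein PMP22 (-2.55), DBI (-2.47), C12orf75 (-2.43), ZCCHC9 (-2.28), LHFPL2 (-2.28), the protease inhibitor SERPINE2 (-2.27) and PARK7 (-2.26), with adjusted p from 0.00881 to 0.0431. TMEM50A was at 94.7 FPKM in A375 scrambled, 11.8 with ETV1-sh1 and 119 with ETV1-sh2. The higher ones were GRAMD1B (3.05), SH2D2A (2.69), synaptophysin (SYP, 2.55), PRR9 (2.46), SERPIND1 (2.30), ESM1 (2.22), DYNLRB1 (2.14), calretinin (CALB2, 2.08), MED19 (2.02) and PTBP2 (1.998), with adjusted p from 0.0157 to 0.0431.

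After ETV1-sh2 the lower genes with the largest changes were ETV1 (-4.15), thymidylate synthase (TYMS, -4.11), the plasminogen activator PLAT (-3.43), HDDC2 (-3.32), ENC1 (-3.25), RRM2 (-3.13), TIMP3 (-3.10), ANXA2 (-3.08), the cytokinesis protein ANLN (-3.04) and COX5A (-2.76), with adjusted p from 0.00299 to 0.0256. PLAT was at 239 FPKM in A375 scrambled, 95.6 with ETV1-sh1 and 14.4 with ETV1-sh2, and at 1005, 445 and 133 in Colo800. The higher ones were SPINT1 (2.98), the mucin MUC1 (2.90), MAP7 (2.57), PANX2 (2.54), DYNLRB1 (2.48), CDC42BPG (2.46), the interferon-induced IFIT1 (2.44), FBXO2 (2.38), LIPH (2.34) and SNX15 (2.22), with adjusted p from 0.00415 to 0.0368. The counts moved by over 1.5 times under several alternatives. With no filter on low values no gene passed for either hairpin (smallest adjusted p = 0.0638 for ETV1-sh2). Without the A375 scrambled library 1 gene fell and 1 rose with ETV1-sh1, and 64 fell and 19 rose with ETV1-sh2; without the Colo800 scrambled library the numbers were 1 and 0, and 224 and 98. Each fit without a library has 1 residual degree of freedom, and a hairpin left with 1 library adds nothing to the spread. Without either ETV1-sh1 library 0 genes passed with ETV1-sh1 and at most 531 fell and 352 rose with ETV1-sh2, and without either ETV1-sh2 library up to 502 fell and 332 rose with ETV1-sh1. With no variance trend 87 fell and 32 rose with ETV1-sh1, and in the 3865 genes without a 3′ UTR match 0 passed with ETV1-sh1, and 245 fell and 322 rose with ETV1-sh2.

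The gene lists were tested in the same fit. After ETV1-sh2 22 of the 29 DNA replication genes fell and none rose (median -1.24, camera adjusted p = 1.37e-13, adjusted p = 0.75 with an estimated correlation; 24 adjusted over the list alone), among them UHRF1 (-2.49), PCNA (adjusted p = 0.0158), RRM2 and MCM10 (-2.71). Of the 28 proliferation genes 20 fell (median -1.61, adjusted p = 0.75 with an estimated correlation; 27 adjusted over the list alone), among them MAD2L1 and NUSAP1. Of the 27 ribosome biogenesis and MYC genes 13 fell (median -0.75, adjusted p = 0.75 with an estimated correlation; 22 adjusted over the list alone), MYC itself from 14.8 to 1.76 FPKM in A375 and from 52.7 to 12.4 in Colo800. Of the 30 interferon response genes 15 rose (median 1.22, adjusted p = 0.75 with an estimated correlation; 20 adjusted over the list alone). Of the 27 ERK output genes 8 fell and 1 rose (14 and 1 adjusted over the list alone), of the 27 glycolysis and hypoxia genes 8 fell (8), of the 37 extracellular matrix genes 8 fell and 1 rose (11 and 2), and of the 24 melanocyte lineage genes 6 fell (6). Of the 16 housekeeping genes TUBB (-1.66), TUBA1B (-0.87), PPIA (-0.68) and YWHAZ (-1.58) fell (median of the list -0.23, camera adjusted p = 0.0282, adjusted p = 0.75 with an estimated correlation; 5 adjusted over the list alone). Of the 16 ETS factors ETV1, ETV3 (-0.86), ETV6 (-1.46) and ELK3 (-2.10) fell (median -0.63, camera adjusted p = 0.0119, adjusted p = 0.75 with an estimated correlation). The housekeeping genes, ETV3 and ELK3 were chosen after their values were seen. The fibroblast markers COL1A1 (1.88), PDGFRB (1.25) and LUM (0.92), chosen after their values were seen, rose (3 of 6), with PDGFRB at 3.11 FPKM in A375 scrambled and 6.99 with ETV1-sh2.

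After ETV1-sh1 no proliferation, DNA replication, ribosome biogenesis or interferon response gene passed over all genes, though 28 of 28, 21 of 29 and 23 of 27 members of the first 3 lists were negative and 27 of 30 of the last positive (camera adjusted p from 2.15e-05 to 0.0186, adjusted p = 0.964 with an estimated correlation). Adjusted over the list alone 4 proliferation genes (CCNB2, NUSAP1, MAD2L1 and HMMR) and 4 DNA replication genes (MCM10, TYMS, CCNE2 and UHRF1) fell, of which CCNB2 and CCNE2 were chosen after their values were seen. The ERK output genes HMGA2, TFAP4 and ETV5 fell (3 of 27; 7 fell and 1 rose adjusted over the list alone). ETV5, a close relative of ETV1, was at 70.3 FPKM in A375 scrambled, 24.5 with ETV1-sh1 and 55.7 with ETV1-sh2, and at 186, 60.7 and 93.4 in Colo800. Cytosolic ribosomal protein genes were positive in 45 of 51 members with ETV1-sh1 (median 0.20, camera adjusted p = 0.000457, adjusted p = 0.964 with an estimated correlation) and negative in 47 of 51 with ETV1-sh2 (median -0.36, camera adjusted p = 2.04e-06, adjusted p = 0.854 with an estimated correlation). With ETV1-sh2 RPL15 nevertheless rose (adjusted p = 0.04) and RPL5 (-1.19), RPS13 (-1.22) and RPS24 (-0.93) fell, all 4 chosen after their values were seen. Adjusted over the list alone 2 members fell and 0 rose with ETV1-sh2. RPL15 was also higher with ETV1-sh1, by 0.72 in A375 and 1.02 in Colo800.

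In this fit 58 genes fell with both hairpins, among them ETV1, TIMP3, PSAT1, HMGA2, MMP16, PABPC1, BAMBI, S100B, LAMC1 and PFKFB3, and 58 rose with both, among them DYNLRB1, MED19, FURIN, HOXC6, CLU, LATS2 and SLC7A1. Independent lists of those lengths would share 15.1 and 6.65 genes. Both contrasts use the same 2 scrambled libraries. In simulated data with no hairpin effect 0.2 genes passed with both hairpins on average, and at most 2. Part of the excess can come from the shared scrambled libraries, which cannot be split.

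Within each line, genes were counted that both hairpins changed at least 2-fold in the same direction. In A375 181 genes were lower and 106 higher, in Colo800 101 lower and 100 higher, and simulated libraries with no hairpin effect gave 27.8 and 25.1 such genes per line. In A375 the genes with the largest smaller change were TIMP3, the sulfate transporter SLC26A2 (174 FPKM scrambled, 13.5 and 15.9 with the hairpins), ART3 (43.4, 3.91 and 2.27), the matrix link protein HAPLN1 (133, 14.3 and 1.06), the transcription factor TFAP2B (32.1, 4.03 and 2.68) and the VEGF receptor FLT1 (16.6, 1.85 and 1.35) among the lower. CEP97 (8.84, 89.6 and 117), DYNLRB1, SNX15, MED19, IFI44 (9.56, 41.3 and 47.2) and CEACAM1 (1.15, 7.36 and 17.7) were highest. In Colo800 they were the natriuretic peptide gene NPPC (17.0, 1.98 and 0.442), FBXL13 (8.94, 1.203 and 1.06), PLA1A (5.72, 0.632 and 0.646), TIMP3, CST1 (12.6, 2.61 and 0.471) and MYO5A (89.4, 24.6 and 24.5), and on the higher side GRAMD1B (1.15, 34.5 and 12.2), FURIN, DYNLRB1, MED19, TMED4 (43.4, 181 and 166) and the ephrin EFNB2 (0.82, 5.04 and 5.18).

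Both lines shared 26 of the lower genes, where chance overlap of independent lists gives 1.64, and 27 of the higher, where it gives 0.95, while 1 gene went opposite ways. With a pseudocount of 0.1 the lines shared 42 lower and 71 higher genes, with 230 higher in A375 and 250 in Colo800, and in genes without a 3′ UTR match they shared 3 and 17, from 66 lower and 55 higher in A375 and 16 and 53 in Colo800. The lower ones include ETV1, TIMP3, PSAT1, HMGA2, MMP16, PABPC1, BAMBI, PLAT, RRM2, UHRF1, GDF15 and HK2, and the higher ones DYNLRB1, MED19, FURIN, HOXC6, IFI44, LIPH, GRAMD1B and the autophagy kinase ULK1. As a reference, the library of another hairpin was set apart in place of scrambled. With ETV1-sh1 set apart from the other libraries 84 genes were shared by the lines, and with ETV1-sh2 set apart 271, against 53 with scrambled set apart.

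Across the 11129 genes, which are not independent replicates, changes with the same hairpin correlated between lines at 0.526 (Spearman 0.485) for ETV1-sh1 and 0.656 (0.674) for ETV1-sh2. These pairs share no library. Changes with different hairpins in different lines correlated at 0.2 (ETV1-sh1 in A375, ETV1-sh2 in Colo800; Spearman 0.207; covariance 0.0698) and 0.263 (Spearman 0.275; covariance 0.107). Within a line, where both changes share the scrambled library, the correlations were 0.38 in A375 and 0.39 in Colo800, with covariances of 0.156 and 0.136. Unchanged libraries with a shared control gave a correlation of 0.503 and a covariance of 0.0591 in simulation.

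**Figure D4:**
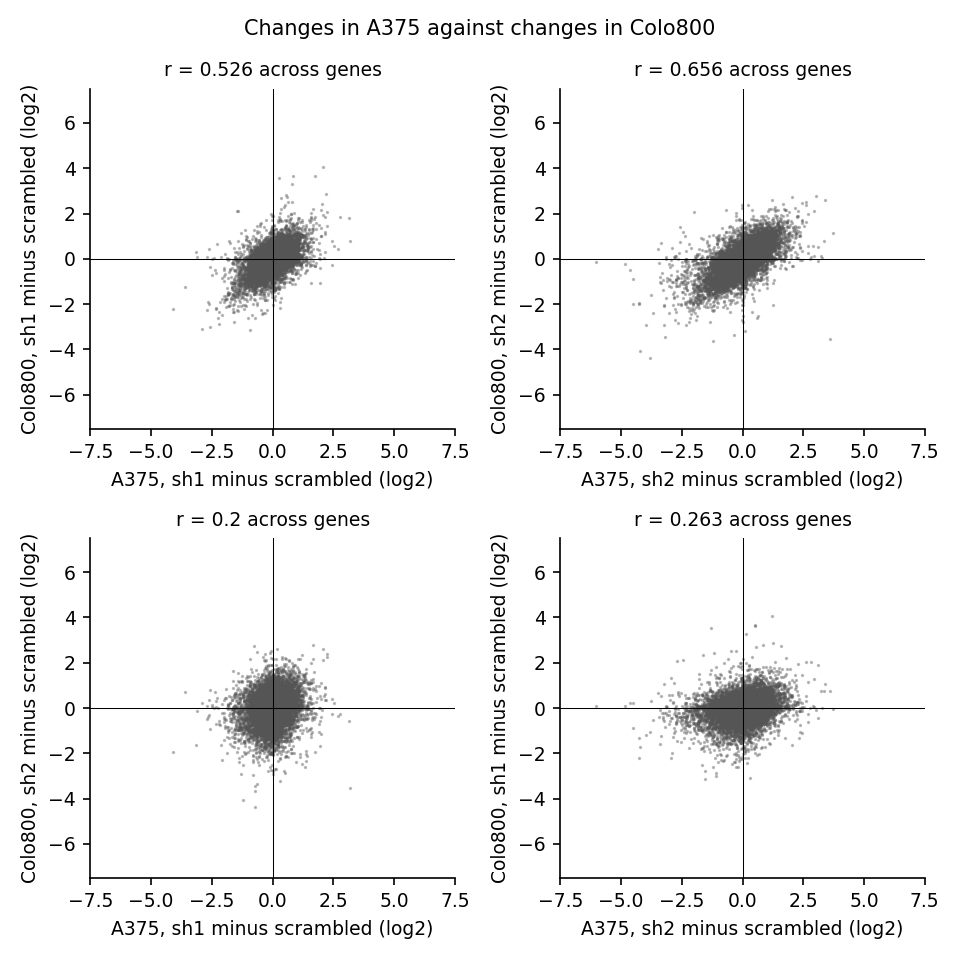
Change of each of the 11129 genes in log2(FPKM + 1), ETV1 hairpin minus scrambled, in A375 (x axis) and Colo800 (y axis), 1 point per gene. The upper panels show the same hairpin in both lines (r = 0.526 and 0.656) and the lower panels different hairpins (r = 0.2 and 0.263).

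The hairpins were compared with each other in both lines, a contrast that in the labels also carries the drug labels DMSO and trametinib. Relative to ETV1-sh1, 769 genes were lower and 759 higher with ETV1-sh2. COX5A, a subunit of cytochrome c oxidase, was at 71.5 FPKM with ETV1-sh1 and 7.004 with ETV1-sh2 in A375, and at 108 and 8.06 in Colo800 (log2 difference -3.38, SE 0.176, adjusted p = 0.00426). The other largest lower differences were urocortin 2 (UCN2, -3.33), TYMS (-3.22), SLAMF9 (-2.88) and ESM1 (-2.84). The largest higher differences were TMEM50A (3.27), the imprinted gene NDN (2.88), the epoxide hydrolase EPHX1 (2.64), LIMCH1 (2.51) and FBXO2 (2.50). ETV1 itself differed by -2.68 (adjusted p = 0.00553). No gene passed with no filter on low values, nor without either ETV1-sh1 library, where that hairpin is left with 1 library.

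Whether the effect of the ETV1 hairpins differed between lines was tested as an interaction. No gene passed in limma (smallest adjusted p = 1), and 66 had an unadjusted p under 0.05 where chance gives 556. The simulated test had no power at 4-fold, so differences of that size are not excluded. The smallest p-values on the side of a lower effect in Colo800 belonged to FBXL13 (log2 difference of effects -2.36, SE 0.513), PLA1A (-2.05, SE 0.46) and the small heat shock protein CRYAB (-2.001, SE 0.6). On the other side they belonged to carbonic anhydrase CA9 (2.88, SE 0.489), TFAP2B (3.03, SE 0.549) and TIMP3 (2.11, SE 0.452).

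The lines themselves differed far more than the hairpins within them. Averaged over the 3 hairpins, 2811 genes were lower and 3542 higher in Colo800 than in A375. That excess of higher genes turned with quantile normalization (3128 lower, 3066 higher) and with equal medians (3241 lower, 3168 higher). The interstitial collagenase MMP1 stood at 3017 to 10733 FPKM in Colo800 and 4.29 to 10.7 in A375 (log2 difference 9.75, SE 0.27, adjusted p = 1.7e-05). Fibronectin (FN1, 6.67), SERPINB2 (6.55), the melanin synthesis gene DCT (6.44) and the integrin activator FERMT3 (6.397) followed. The long noncoding RNA UCA1 (-7.84), the decoy receptor IL13RA2 (-7.75), GTSF1 (-7.08), the cancer-testis gene MAGEC2 (-6.95) and the aminopeptidase ANPEP (-6.32) were the lowest. Without the A375 scrambled library 1831 genes were lower in Colo800, and without the Colo800 scrambled library 1855.

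Among the lists, 28 of 28 proliferation genes and 22 of 24 melanocyte lineage genes were higher in Colo800 (medians 2.21 and 1.87), as were 27 of 32 integrated stress response genes (median 1.31), 22 of 29 DNA replication genes (median 1.15) and 17 of 22 unfolded protein response genes (median 0.97). Lower in Colo800 were 21 of 24 p53 targets (median -1.99), 37 of 51 cytosolic ribosomal protein genes (median -0.84), 14 of 30 interferon response genes (median -0.66) and 7 of 10 replication-dependent histones (median -0.88). Each of these lists passed with camera at the preset correlation (adjusted p from 2.83e-09 to 0.00775), and none with an estimated correlation (adjusted p from 0.723 to 0.883). With fry's directional test they passed (adjusted p from 0.022 to 0.0308), except proliferation (0.0746) and interferon response (0.172). Glycolysis and hypoxia genes were higher in 16 and lower in 2 of 27 (median 0.64). Of the 12 epithelial and 14 keratinocyte markers only 4 and 4 were expressed enough to be tested, and all of those were lower. These counts stand beside 3542 higher and 2811 lower among all 11129 genes tested.

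The drug labels were examined through the ERK output list, since inhibitors of MEK and BRAF lower it. The median log2 difference over its 27 genes, ETV1-sh2 minus ETV1-sh1, was -0.49 in A375 (95% bootstrap interval over genes -1.10 to -0.16, 20 genes lower) and -0.21 in Colo800 (-0.69 to 0.19, 17 genes lower). The median of scrambled minus ETV1-sh1 was 0.36 in A375 (-0.16 to 0.53) and 0.36 in Colo800 (-0.14 to 0.58). The feedback phosphatase DUSP6 stood at 201 FPKM with the scrambled hairpin, 166 with ETV1-sh1 and 118 with ETV1-sh2 in A375, and at 156, 95.9 and 138 in Colo800. SPRY4, a feedback inhibitor of the pathway, was at 228, 290 and 86.6 in A375 and at 516, 281 and 174 in Colo800.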

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

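The tests on library depth, on words of the 3′ UTR and on the scrambled hairpin in this closing section were chosen after the results were seen. Among 25 genes of the comparison with scrambled, 1 had a change far from its other 3: SNX15 was higher by 1.46 on the log2 scale with ETV1-sh1 in Colo800, while its changes in the other 3 libraries lay close together. Chance gives such a gap in about 1 of 20 sets of 4 values.

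For 3 genes named within a line both hairpins went one way in A375 and the other way in Colo800, and the interaction fit called none of them. TFAP2B changed by -2.94 on average in A375 and by 0.08 in Colo800, where it was at 0.07 FPKM or lower. PLA1A changed by 0.011 in A375, where it was near 0.02 FPKM, and by -2.04 in Colo800. CST1 changed by 0.2 in A375, where it was listed at 0 with the scrambled hairpin, and by -2.56 in Colo800. Each of these 3 genes was near the floor in the line where it moved little. CEP97, well above the floor, was higher in A375 with both hairpins (8.84, 89.6 and 117 FPKM) but went both ways in Colo800 (159 FPKM with scrambled, 271 with ETV1-sh1 and 12.8 with ETV1-sh2).

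Genes moved by 1 hairpin in both lines were weighed first. A difference in library depth argues the other way: the ETV1-sh2 library is deeper than the ETV1-sh1 library in A375 and shallower in Colo800, yet the differences between the hairpins correlated at 0.606 between lines across genes. The drug labels go with the same split of the libraries. Matches between 3′ UTRs and the hairpins' targets are tested among the other observations.

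The drug labels were weighed on the ERK output genes, with the predictions written before the result was seen. For the MEK inhibitor in the ETV1-sh2 libraries the list was predicted to lie below -1 in both lines, with DUSP6 and SPRY4 lower, and a median above -0.5 in at least 1 line was written as the mark against it. Both medians met that mark as written, the higher being -0.206, in Colo800. The script's rule, also written before the values were seen, asked in addition that the interval lie above -0.5, and neither did (-1.10 to -0.16 in A375, -0.69 to 0.19 in Colo800), so the MEK inhibitor is left open, although the predicted size was reached in neither line and DUSP6 was higher with ETV1-sh2 than with ETV1-sh1 in Colo800 (138 against 95.9 FPKM). A stricter reading against -1 was tried after the values were seen; it would exclude the predicted size in Colo800 but not in A375, and it is not used here. For the BRAF inhibitor in the scrambled libraries the higher median was 0.365, opposite in sign to the prediction, and both intervals lay above -0.5. The reference in both checks is the ETV1-sh1 library, which itself carries an ETV1 hairpin. In the fit with 3 hairpin levels the list's median was -0.267 for ETV1-sh1 against scrambled. Drug and hairpin effects cannot be separated here, so the positive sign does not exclude a drug effect.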

How the results depend on the processing

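Each hairpin against scrambled, and the fits on genes without a 3′ UTR match, were chosen after the data were seen. No fold change or median changed sign under any alternative run, though the balance of higher against lower genes turned for several comparisons, among them Colo800 against A375 and ETV1-sh2 against scrambled. Absolute depth is unknown, so low genes are limited by an unmeasured amount. For ETV1 hairpins against scrambled and for the interaction, 0 genes passed under each pseudocount, filter, scaling, variance and left-out-library alternative run, and for the first also with no replicate block (cell line left out), where ETV1 stayed at -2.81. With ETV1-sh1 and scrambled libraries only, 489 genes fell and 316 rose and ETV1 was at -1.47; with ETV1-sh2 and scrambled libraries only, 527 fell and 363 rose and ETV1 was at -4.15. In these fits the gap between hairpins is no part of the spread, and 1 residual degree of freedom is left.

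With no filter on low values 0 genes passed, lower or higher, for ETV1-sh2 against ETV1-sh1 and for each hairpin against scrambled; that fit had 2.07 prior degrees of freedom in place of 4.32 and tested 16132 genes. With no variance trend 87 genes fell and 32 rose with ETV1-sh1. In the 3865 genes without a 3′ UTR match 123 were lower and 111 higher with ETV1-sh2 than with ETV1-sh1, 0 fell and 0 rose with ETV1-sh1, and 245 fell and 322 rose with ETV1-sh2, where more fell with all genes (1002 against 860). Changed 2-fold by both hairpins there were 66 lower and 55 higher in A375, 16 and 53 in Colo800, and 3 and 17 in both lines. Fewer genes were tested there. For lists of ETV1 hairpins against scrambled, camera with an estimated correlation and fry's directional test each left 0 lower and 0 higher. The first of these rests on 3 residual degrees of freedom, so a miss there decides little.

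Within lines, a 1.5-fold limit gave 555 lower and 494 higher in A375, 466 and 520 in Colo800, and 164 and 179 in both. A 3-fold limit gave 26 and 15, 13 and 14, and 2 and 4. A pseudocount of 0.1 gave 230 higher in A375, 250 higher in Colo800, and 42 lower and 71 higher in both; it enlarges the changes of low genes.

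Leaving out each library in turn, ETV1 ran from -3.46 to -2.18 over both hairpins. Genes lower in Colo800 than in A375 ran from 1831 to 2523. With all libraries the excess of genes higher in Colo800 (3542 against 2811) was absent with quantile normalization (3066 higher, 3128 lower) and with equal medians (3168 higher, 3241 lower). ETV1-sh2 against ETV1-sh1 ran from 0 to 891 lower and 0 to 848 higher. ETV1-sh1 against scrambled ran from 0 to 502 lower and 0 to 332 higher, and ETV1-sh2 against scrambled from 64 to 1058 lower and 19 to 916 higher. Higher lists of ETV1 hairpins against scrambled ran from 1 to 2. Each of these fits has 5 libraries in place of 6; those with the 3 hairpin levels keep 1 residual degree of freedom, with no spread from the hairpin left with 1 library. More genes passed with ETV1-sh1 without an ETV1-sh2 library; the cause was not tested.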

Other observations

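Within lists that did not pass with camera, single members changed with 1 hairpin. Of the 38 oxidative phosphorylation genes the succinate dehydrogenase subunits SDHD (log2 change -1.79) and SDHB (-1.29) fell with ETV1-sh1, while 24 of 38 were positive (median 0.07, camera adjusted p = 0.546). With ETV1-sh2 COX5A (-2.76), ATP5D (-1.23) and NDUFV2 (-0.74) fell, while 22 of 38 were positive (median 0.06, camera adjusted p = 0.769). Of the replication-dependent histone genes 3 of 10 rose with ETV1-sh2, HIST1H2BD by 2.06, HIST1H2AC by 1.44 and HIST2H2BE by 1.06, where 22 of 29 DNA replication genes fell (histone list, camera adjusted p = 0.0789). Only 10 of the 15 histone genes of that list were tested. HIST1H4C, HIST1H1B, HIST1H3B and HIST1H4B were below 1 FPKM in every library and were not, so the list covers these genes in part. All genes named in this paragraph were chosen after their values were seen.

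The scan of 3′ UTR words was chosen after the results were seen. It tests whether each hairpin also lowers transcripts whose 3′ UTR matches a short stretch of its target. In A375 the 3′ UTR word whose carriers were lowest with ETV1-sh1 was CTAAACA (1286 genes, statistic -16.5), and in Colo800 it ranked 2 of 16184 words (statistic -16.3), behind an overlapping word, so the prediction of the first rank, itself written after the words were seen, was missed by 1 place. For ETV1-sh2 the word was ATGAACA (statistics -12.6 and -13.0), first in both lines. Both words occur in ETV1, the first in its 3′ UTR and the second in its coding part, though 33.2% of all words occur there by chance. Simulated scans without an effect reached -4.80.

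The prediction that longer matches go with larger changes was written before it was tested, and the order of the means followed it in both lines for both hairpins. Both words were picked in these libraries for their carriers' fall. A larger fall with 7 or 8 bases than with 6 was therefore largely fixed. The means below, unlike the scan, were not corrected for 3′ UTR length and GC content. Like the scan, they compare a hairpin's library with the mean of the other libraries of its line. They therefore also hold the other ETV1 hairpin's effect with opposite sign. The calls and correlations further on are against scrambled. Genes with no match in any part changed by -0.012 (A375) and 0.11 (Colo800) with ETV1-sh1, and by 0.168 and 0.093 with ETV1-sh2. With ETV1-sh1 genes with an 8-base match changed by -0.22 (SE 0.0204, 910 genes) in A375, genes with a 7-base match only by -0.16 and genes with a 6-base match only by -0.005, and the smallest gap between 8-base and 6-base matches in any of the 4 cases was -0.161. The step from 7 to 8 bases lay within its 95% interval in each case (with ETV1-sh1 from -0.161, SE 0.0278, to -0.217 in A375 and from -0.258, SE 0.0271, to -0.314 in Colo800; with ETV1-sh2 from -0.253, SE 0.0258, to -0.269 and from -0.147, SE 0.0213, to -0.172). Genes with the word in the 5′ UTR only (18 and 27 genes) lay above those with it in the 3′ UTR only in 4 of 4 cases, by at least 0.111. The gap passed its 95% interval with ETV1-sh1 in Colo800 (0.016, SE 0.105, against -0.286) and with ETV1-sh2 in A375 (0.182, SE 0.119, against -0.223) and Colo800 (0.263, SE 0.107, against -0.133), but not with ETV1-sh1 in A375 (-0.093, SE 0.0803, against -0.204). The rule set beforehand asked for a gap beyond its interval in all 4 cases. The words were picked for the fall of their 3′ UTR carriers, so part of this gap was fixed too. The 5′ UTR class also leaves out genes with a 6-base match in the 3′ UTR, and the SEs run over genes, not libraries. These uncorrected values from few genes therefore do not decide whether a word acts alike in the 5′ and 3′ UTR. Genes with the word in the coding part only changed by -0.026 in A375 and -0.069 in Colo800 with ETV1-sh1, against -0.204 and -0.286 for the 3′ UTR only. With ETV1-sh2 they changed by -0.118 and -0.078, against -0.223 and -0.133. Counted from genes with no match in any part, coding-part genes lay at -0.014 and -0.179 with ETV1-sh1, against -0.192 and -0.396 for the 3′ UTR only. With ETV1-sh2 they lay at -0.285 and -0.171, against -0.391 and -0.227. Matches may account for part of the pattern, and how much is open. Of the 166 genes with a 3′ UTR that passed as lower with ETV1-sh1, 47.6% carry its word, against 11.3% of genes not called. Of the 988 that passed as lower with ETV1-sh2, 26.0% carry its word, against 14.0%. Among genes that passed as higher, 3.53% and 6.39% carry the word of that hairpin. The words come from these same libraries, so such shares are descriptive. In the 3865 genes with no 6-base match to either word the changes with the same hairpin correlated between lines at 0.451 and 0.641, where different hairpins in different lines gave 0.247 and 0.28.

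Genes moved by both hairpins in both lines may follow from loss of ETV1 or from 3′ UTR matches to the 2 ETV1 hairpins. They may also follow from an effect of the scrambled hairpin or from some other difference of the scrambled libraries. The data leave all of these open. The prediction for loss of ETV1, written before the test, was a larger change with ETV1-sh2, which left less ETV1 mRNA. Among the 286 genes other than ETV1 that both hairpins changed 2-fold in A375, the change in Colo800 in the same direction had a median of 0.68 with ETV1-sh1 and 0.80 with ETV1-sh2, where the median absolute change of all genes was 0.291 and 0.386, also larger with ETV1-sh2. The median difference was 0.052 (95% bootstrap interval -0.03 to 0.172), which does not decide, all the more as any gene would tend that way. No word stood out for the scrambled hairpin as for the others (lowest mean statistic -4.10), but a word carried by 50 genes would reach only -2.25 at the effect size seen, so such an effect is not excluded; that bound was set after the value was seen. Of the 25 lower genes of this group with a 3′ UTR, 36.0%, 28.0% and 0% carry the word of ETV1-sh1, of ETV1-sh2 and the lowest word of scrambled. Of the 27 higher genes 3.7%, 0% and 14.8% do, and of all genes 11.8%, 14.5% and 2.5%. Both ETV1 words occur in 4 of the 25 lower genes and in 0 of the 27 higher, against 3.79% of all genes. The words were picked in these same libraries, so these shares decide nothing.

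For Colo800 against A375, the 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. Without the hairpin term the real split gave 3529 genes, 1 split in all gave as many, and the highest of the others gave 0.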
